A study of Mus musculus with 6 samples.

How the data were processed

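MicroRNA (miRNA) levels were measured in 4T1 cells, a mouse mammary carcinoma line, and in the exosomes these cells release. Exosomes are small vesicles of endosomal origin, and neutral sphingomyelinase 2 (nSMase2) is an enzyme that makes ceramide and takes part in their formation. The 6 arrays came from 3 lines, which carried an shRNA against nSMase2 (KD), an expression vector for nSMase2 (OE) or were the control. Each line gave 1 array of cellular RNA and 1 array of exosomal RNA, so each of the 6 groups held 1 array. Per the labels' protocols, the cells grew in RPMI1640 with 10% fetal calf serum and 100 ng of each RNA was labelled with Cy3 for a 1-colour Agilent array. How the exosomes were isolated, and whether the medium was freed of serum vesicles before collection, is not given in the sources used here. An array of miRNAs does not measure the nSMase2 mRNA, so the KD and OE labels were taken as given.

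The authors' files hold the scanner output of Agilent Feature Extraction 10.7.3.1, per the file headers and the submitters' processing notes, as intensity values on a linear scale. Per the file headers, the processed intensity of each spot was background-subtracted and detrended within its array, with no step between arrays. The deposited value table held the same intensity values: 100% of its cells lay within 1% of the processed intensity on each array, with column medians of 0.85 to 3.87, on the linear scale, not centred. The deposited files also carry flags of the software, listed as other values per the file headers, for spots well above background, outliers and saturation. Each array held 47160 spots that were not controls, for 2982 probes of 1179 miRNA entries, 1122 of mouse and 57 of mouse herpesviruses. Coordinates are those of the files, on the mouse build mm9, and miRNA names are those of the array design. No per-sample column was left unused.

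Outlier spots were left out, and the remaining spots of a probe were averaged on each array. These means were divided by the array's 75th percentile over the 394 probes detected on all 6 arrays, raised to a common floor of log2 -4.80, and put on the log2 scale. A probe counted as detected where over 50% of its spots were well above background. A miRNA took its brightest probe and counted as detected where any of its probes was. No spot was saturated. The number of arrays limits the precision. The standard error (SE) of the spots on an array covers technical error only. The median SE of a log2 ratio was 0.023 to 0.029, and says nothing of the spread between cultures. All 6 arrays were on 1 slide and from 1 scan, so neither could be set as a block.

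Exosomal and cellular RNA were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with the line as a block, over miRNAs detected on all 3 arrays of at least 1 compartment. A Benjamini-Hochberg adjusted p under 0.05 was called. The fit has 2 residual degrees of freedom before moderation. The 3 lines, each cultured once as far as the labels say, stand in for replicates. The p-values measure how the exosomal minus cellular difference varies between the lines. For a miRNA at the floor on all 3 arrays of 1 compartment, such as miR-451, only the other compartment adds to that spread. miRNAs at the floor on every array were left out of this test, a choice made after seeing the data. For a miRNA detected on no array of 1 compartment, the fold is a bound: the mean log2 signal of the other compartment over, per array, the higher of the lowest detected signal and the miRNA's own. KD and OE were each compared with control within a compartment. With 1 array per group no test was made and no p-value is given. A miRNA detected on both arrays was counted at 2-fold or more. miRNAs ordered with nSMase2 were at least 1.5-fold lower in KD and at least 1.5-fold higher in OE than control. The export ratio is the exosomal minus the cellular log2 level of a line.

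The 25 lists of miRNAs, the tests, the rule for named miRNAs and most alternatives were fixed before the data were examined. The lists held miR-210 by itself, miRNAs reported to promote or restrain angiogenesis, miRNAs reported to promote metastasis, the miR-200, let-7, miR-17~92, miR-15/16, miR-232724, miR-29, miR-30 and miR-34 families, the Dlk1-Dio3 and Sfmbt2 clusters, miRNAs often reported in vesicles, entries later traced to tRNA or rRNA fragments, high-GC entries and viral miRNAs. Markers of erythroid cells, liver, leukocytes, endothelium, muscle, neurons and fibroblasts stood for other sources. In the compartment comparison lists with at least 3 tested members went to limma's camera with a preset correlation of 0.01. In the KD and OE comparisons the median log2 ratio of a list was placed among 10000 random lists of the same size matched on signal in 5 bins, which describes these arrays only. Because both ratios share the control array, unchanged arrays were simulated 1000 times with the spread of the cellular arrays. Of the named miRNAs, the compartment comparison took the 10 highest and 10 lowest called log2 ratios with the same sign in all 3 lines. Each KD or OE comparison took up to 10 per direction at 2-fold or more and over 2 SE of the spots, and up to 5 per direction detected on 1 array only. miR-210 and up to 4 members per list were added, and the text gives a part of all these.

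The limma comparison and the placing of lists were tested on simulated data, the other steps were not. In 298 simulated miRNAs with 1 residual SD of 0.244 for all, limma recovered 20 of 20 changes at log2 sizes of 1, 2 and 3, with 4 false calls. A version added after the first used the residual SDs of the single miRNAs, dealt out among them at random. There limma recovered 13 of 20 at 1, 17 of 20 at 2 and 17 of 20 at 3, with 3 false calls. A list of 9 miRNAs shifted by log2 1 among 248 fell at percentile 99.995, against 91.5 unshifted. The alternatives were other scalings (percentile over all probes, none, quantile), normexp background correction with an offset of 50, other summaries (the mean over probes, the software's summed signal) and detection rules, the deposited value table, other thresholds, other limma fits and each line left out in turn. Scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.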

Results

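miRNA levels were available for cellular and exosomal RNA of nSMase2 knock-down (KD), control and nSMase2-overexpressing (OE) 4T1 cells, with 1 array in each of 6 groups. The mean processed signal was 152.1, 146.5 and 159.0 on the cellular arrays of KD, control and OE, and 252.6, 828.8 and 242.3 on the exosomal arrays. The control exosomal array was thus the brightest, and its 75th percentile over detected probes was 2784, against 639.7 for KD and 597.4 for OE exosomes. Of 1179 entries, 261, 262 and 238 were detected in KD, control and OE cells, and 443 in control exosomes, with at least 318 in those of KD and OE. All 6 arrays detected 217 entries. Another 45 were detected on all 3 exosomal arrays and on no cellular array, and 1 on all 3 cellular arrays and on no exosomal array. Entries for miRNAs of mouse herpesviruses, which 4T1 cells should lack, were detected 4 times on each cellular array and 5, 12 and 8 times on the KD, control and OE exosomal arrays.

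The first comparison asked which miRNAs exosomes hold at other levels than the cells they come from. The highest ratio was that of miR-451, made in erythroid cells, which was detected on no cellular array and was at least 1461-fold higher in exosomes (fitted log2 ratio to the floor 10.33, limma adjusted p = 0.0036, n = 3 lines, higher in 3 of 3). Its cluster partner miR-144-3p was at least 32.4-fold higher and the leukocyte miRNA miR-142-3p at least 46.5-fold higher, both with limma adjusted p = 0.0036. miR-223-3p, a myeloid miRNA detected on 2 of 3 cellular arrays, was 5.07 higher on the log2 scale, a minimum value because control and OE cells were at the floor, and the endothelial miR-126-3p 3.20 higher (SE 0.29). On the cellular side, miR-494-3p was 9.37-fold lower in exosomes (log2 ratio -3.23, SE 0.13, limma adjusted p = 0.0036), miR-3096b-3p 7.08-fold lower, and miR-5117-3p, detected on no exosomal array, at least 13.3-fold lower. The bounds hold for the processing used here: the fitted log2 ratio to the floor fell with normexp to 8.13 for miR-451, 3.23 for miR-142-3p and 2.73 for miR-144-3p, and for miR-5117-3p, -2.70 here, to -1.08 with normexp and -0.77 with the mean over probes. In all, limma called 36 of 298 tested miRNAs higher in exosomes and 24 lower.

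**Figure D1:**
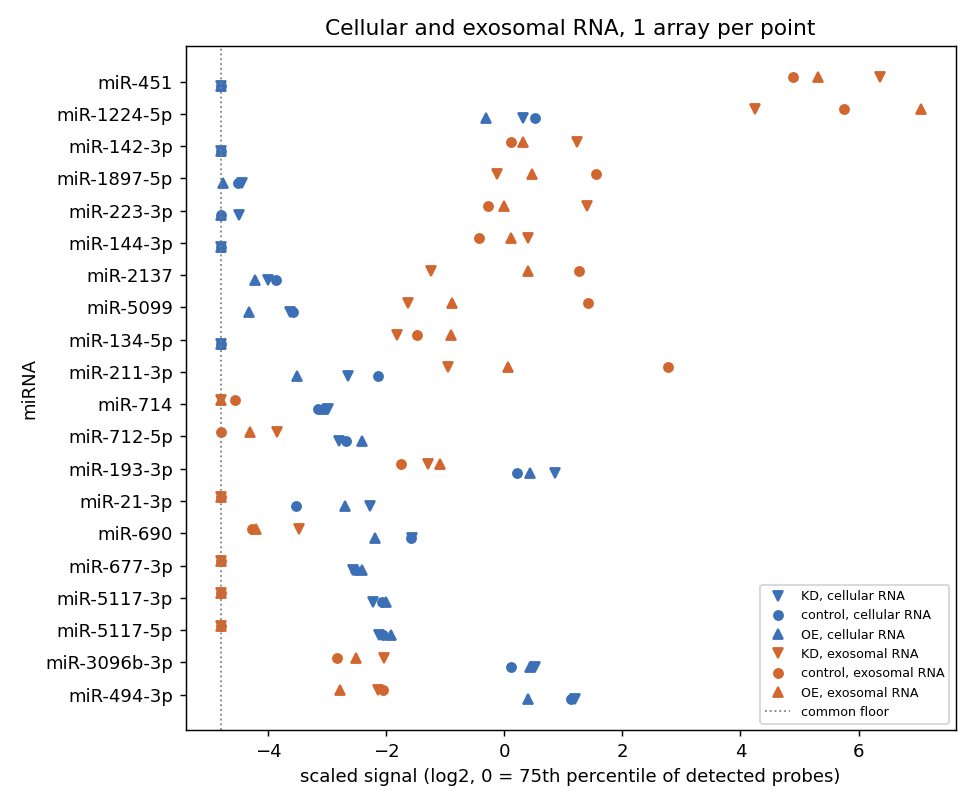
Scaled signal (log2, horizontal axis) of the 20 miRNAs named by the rule for the compartment comparison (vertical axis), 1 point per array, with cellular RNA in blue, exosomal RNA in orange and the shape giving the line. The dotted line is the common floor at -4.80; miR-451 lay at it in all 3 cellular arrays and between 4.90 and 6.37 in exosomes.

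Other miRNAs at the top of the exosomal side included miR-1224-5p and miR-2137 of the high-GC list. miR-1224-5p rose by 5.51 on the log2 scale (SE 0.74), miR-1897-5p by 5.20, miR-2137 by 4.17, miR-5099 by 3.47 and miR-211-3p by 3.39, and miR-134-5p of the Dlk1-Dio3 cluster was at least 12.1-fold higher (fitted log2 ratio 3.41, or 1.47 with normexp). The call of miR-211-3p (limma adjusted p = 0.049) was kept in 10 of 18 alternatives. Exosomal levels had an SD of 1.93 for miR-211-3p and 0.42 for miR-144-3p (n = 3 lines). The lower side held miR-677-3p, miR-690, miR-193-3p, miR-712-5p, miR-714 and the passenger strand miR-21-3p, with log2 ratios from -2.30 to -1.65. The guide strand miR-21-5p, which is abundant in many tumours, had a ratio of -0.04 (limma adjusted p = 0.81). miR-5117-5p, miR-677-3p, miR-21-3p and miR-714 were detected on 1 of 3 exosomal arrays, the control. The first 3 were at the floor on all 3 exosomal arrays and miR-714 on those of KD and OE, so their ratios are minimum sizes.

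Of the lists tested with camera, that of miRNAs often reported in vesicles was higher in exosomes (adjusted p = 0.00088, 5 of 7 tested members called over all miRNAs and 6 adjusted over the list alone). Its adjusted p was 0.88 in camera with an estimated correlation, and 0.00028 with limma's fry, a second list test planned beside camera. Of its members, miR-451, miR-142-3p, miR-223-3p, miR-320-3p and miR-1224-5p passed, and miR-483-5p (adjusted p = 0.054) and miR-146a-5p (adjusted p = 0.12) did not. Of the 9 entries of this list on the array, 7 are also in another list. The high-GC list also passed camera (adjusted p = 0.049, median log2 ratio 1.43, 6 of 15 called higher and 2 lower, 8 and 2 adjusted over the list alone). Its adjusted p was 0.95 in camera with an estimated correlation and 0.16 with fry. An alternative chosen after seeing the data left out the erythroid, liver, leukocyte and endothelial markers and the list of miRNAs often reported in vesicles. There 0 of 15 lists passed camera, and 26 miRNAs were called higher and 24 lower. The vesicle list could not pass, because its members were removed, and the high-GC list lost miR-1224-5p. None of the 17 lists passed with an estimated correlation. The leukocyte list had 2 of 5 members called (camera adjusted p = 0.13). In the miR-29 family, regulators of collagen genes, miR-29b-3p fell by 1.23 and miR-29c-3p by 0.90 on the log2 scale, while miR-29a-3p had a ratio of -0.59 that did not pass, and adjusted over the list alone all 3 passed. Without scaling the ratio of miR-29c-3p, and with it the median of the family, was 0.13. The camera adjusted p of this family was 0.083, that of let-7 was 0.11, and those of the other lists ran from 0.43 to 0.96. These were the lists for angiogenesis, metastasis, miR-200, miR-17~92, miR-15/16, miR-232724, miR-30, Dlk1-Dio3, Sfmbt2, RNA fragments and viral miRNAs. Median and mean differed in sign for the pro-angiogenic list (-0.04 and 0.07), miR-15/16 (-0.02 and 0.05), Sfmbt2 (-0.02 and 0.29) and RNA fragments (0.18 and -0.02), and camera gave the direction up for miR-15/16 and down for the others. The medians of these 4 lists were 0.95 to 1.20 without scaling and -0.64 to -0.41 with the percentile over all probes. Lists with fewer tested members give values only. The liver miRNA miR-122-5p was detected on no cellular array and was at least 4.64-fold higher in exosomes (limma adjusted p = 0.032, fitted log2 ratio 2.03, or 0.47 with normexp), and miR-192-5p did not pass (adjusted p = 0.30). The neuronal list had miR-128-3p called at 0.73, which was -0.073 with quantile normalization, and miR-9-5p at -0.46 not called. miR-199a-3p of fibroblasts (1.31) and miR-208a-5p of muscle (1.18), both at the floor in all cells, and miR-34a-5p (0.21) did not pass. miR-210-3p, induced by hypoxia and reported to promote angiogenesis (mm9 chromosome 7, 148407354 to 148407369, minus strand), had a ratio of -0.99 (SE 0.25, limma adjusted p = 0.072), and of 0.034 without scaling.

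The split of these calls depended on the scaling. It was 32 higher and 90 lower with the percentile over all probes, 75 and 4 without scaling and 21 and 77 with quantile normalization, where the median log2 ratio of all tested miRNAs was -0.41, 0.99 and -0.23, against 0.03 here. Leaving out the OE line ended all calls in limma (0 and 0, with 35 and 28 at an unadjusted p under 0.05), and leaving out the control line gave 62 and 19.

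The next comparison asked how nSMase2 knock-down changed the exosomal miRNAs. All ratios between lines are of single arrays with no replicate check. Members of the Sfmbt2 repeat cluster had the highest ratios. miR-466f-3p was 26.6-fold higher (log2 ratio 4.73, SE of spots 0.02). miR-466h-3p, miR-467f and miR-466i-3p had log2 ratios of 4.71, 4.36 and 4.25, which are minimum values because the control array was at the floor. Of 34 measured members of the cluster 12 were at least 2-fold higher and 0 lower. The list median of 0.60 lay at percentile 98 of matched random lists, though without scaling the median was -1.28. Both the count and the percentile take members as independent, and signal shared between members of this repeat cluster was not tested. miR-709 was 13.1-fold higher. On the other side, miR-5121 had a log2 ratio of -4.17, and miR-1982-5p was 15.6-fold, miR-211-3p 13.2-fold, miR-1949 11.3-fold and miR-483-5p 9.11-fold lower, and miR-705 was at the floor in KD and at least 13.6-fold lower. miR-669c-3p was detected in KD exosomes and not in control (at least 34.6-fold), and miR-721 in control and not in KD (at least 13.7-fold). In all, 53 of 318 miRNAs were at least 2-fold higher and 27 at least 2-fold lower.

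Angiogenic miRNAs are named by the title of the series. miR-210-3p was 2.30-fold lower in KD than in control exosomes (log2 ratio -1.20, SE of spots 0.02) and miR-132-3p, also of the pro-angiogenic list, 4.14-fold lower. The whole pro-angiogenic list had a median of 0.17 at percentile 8.9 (-0.07 with the percentile over all probes and -1.95 without scaling). Of its 24 members 1 was at least 2-fold higher, miR-126-3p (log2 ratio 1.52), and 2 at least 2-fold lower. The leukocyte list had a median of 1.37 at percentile 99.9, which was -0.51 without scaling, with miR-223-3p 3.22-fold and miR-146a-5p 4.15-fold higher, miR-451 was 2.78-fold higher, and the liver list had a median of 1.13 at percentile 94.2, or -0.76 without scaling. The list of miRNAs often reported in vesicles lay at percentile 98.1 (median 0.69, or -0.82 without scaling), but its members went both ways. Of its 8 members 4 were at least 2-fold higher and 2 at least 2-fold lower, with miR-483-5p the lowest (log2 ratio -3.19). It shares miR-223-3p and miR-146a-5p with the leukocyte list, so the percentiles of these lists are not independent. The high-GC list, with a median of -0.96, lay at percentile 0.02. The remaining lists with at least 3 members lay between percentiles 12.3 and 95.6. Without scaling the counts were 12 and 242, the median log2 ratio of all miRNAs was -1.70 against 0.25 here, and the ratios of miR-451, miR-223-3p and miR-146a-5p changed sign, to -0.65, -0.44 and -0.068. With no common floor 82 were higher.

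The same question was asked of nSMase2 overexpression. miR-709 was 39.9-fold higher in OE than in control exosomes (log2 ratio 5.32, SE of spots 0.01), miR-5107 16.2-fold higher and miR-466f-3p 11.5-fold higher. miR-466h-3p and miR-466i-3p had log2 ratios of 3.35 and 3.01, minimum values as above. miR-211-3p was 6.55-fold lower, miR-1982-5p 6.51-fold, miR-5105 5.42-fold, miR-5121 5.06-fold and miR-5099 4.95-fold lower. Of these, miR-5105 is in the list of entries later traced to tRNA or rRNA fragments. Of the pro-angiogenic list miR-31-5p had a log2 ratio of 1.32, which turned to -0.90 without scaling, miR-132-3p was 3.26-fold lower and miR-210-3p 1.19-fold lower (log2 ratio -0.25), and the list median of 0.02 lay at percentile 23.3. This median was -0.24 at percentile 1.5 with quantile normalization, -0.37 with the percentile over all probes and -2.20 without scaling. In all, 38 of 310 miRNAs were at least 2-fold higher and 15 at least 2-fold lower. The high-GC list lay at percentile 0.51 (median -0.37), but its members went both ways. Of its 15 members 5 were at least 2-fold higher, with miR-709 the highest, and 2 at least 2-fold lower. All other lists with at least 3 members lay between 7.1 and 93.7, with the leukocyte list at 77.8. Without scaling the counts were 7 and 255, with a median log2 ratio of -2.06 against 0.10 here, and with no common floor 62 were higher.

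The title of the series asks about effects of nSMase2, and a graded order, KD under control under OE, was seen for 5 of 286 exosomal miRNAs at 1.5-fold, and the opposite order for 0. The 5 were miR-762 (-2.00 in KD and 1.21 in OE, log2), miR-1224-5p (-1.52 and 1.29), miR-208a-5p (-0.72 and 2.08), miR-680 (-1.32 and 1.36) and miR-3081-5p (-1.29 and 0.92). miR-762 and miR-1224-5p belong to the high-GC list, and miR-208a-5p and miR-3081-5p were at the floor in KD. Without scaling the OE ratios of all 5 were below 0, from -1.30 to -0.14, and the count was 1. It was also 1 among miRNAs detected on all 6 arrays. At the same threshold 40 miRNAs were higher in both lines than in control and 19 lower in both, which became 25 and 35 with the percentile over all probes and 8 and 245 without scaling. Both ratios share the control array, and 67.1% of them had the same sign, against 66.6% simulated for unchanged arrays with the spread of the cellular arrays. Their correlation over miRNAs, which are not independent replicates, was 0.74 in exosomes and 0.41 in cells, against a simulated 0.49 and 0.50. The covariance was 0.93 in exosomes (0.47 with normexp) against a simulated 0.12, and 0.086 in cells against 0.12. The exosomal ratios varied more, with variances of 1.60 in KD and 0.98 in OE, against 0.19 and 0.23 in cells. The simulated covariance, with the cellular spread, is therefore no reference for exosomes. For cells its spread came from the same arrays, so no conclusion is drawn from either. The single control array could not be split. Without the control array, a comparison chosen after seeing the data, 29 of 288 exosomal miRNAs were at least 2-fold higher in OE than in KD and 30 at least 2-fold lower, which became 18 and 37 with the percentile over all probes, 47 and 20 with the summed signal per miRNA scaled over miRNAs (31 and 33 in the scaling used here) and 14 and 11 with normexp.

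**Figure D2:**
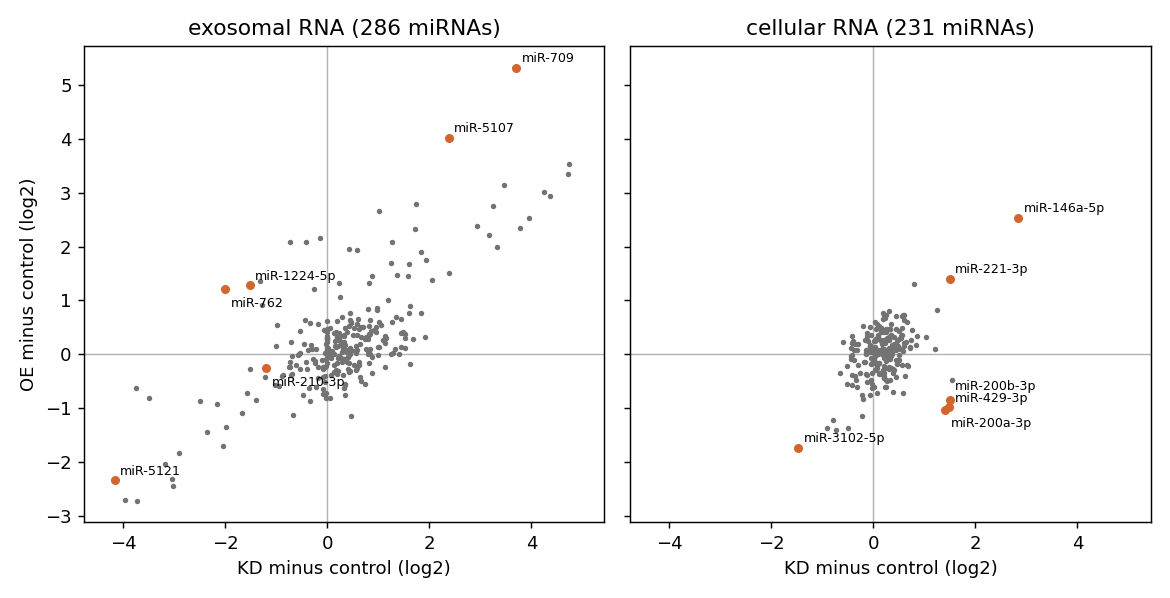
Log2 ratio of KD to control (horizontal axis) against OE to control (vertical axis), 1 point per miRNA detected in all 3 lines, for exosomal RNA (left, 286 miRNAs) and cellular RNA (right, 231 miRNAs), with some named miRNAs in orange. The 2 axes of a panel share the control array, and without scaling 245 exosomal miRNAs lie at least 1.5-fold below control in both lines. In cells miR-200a-3p, miR-200b-3p and miR-429-3p lie at the lower right.

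In cellular RNA the lines differed less. In KD cells 9 of 248 miRNAs were at least 2-fold higher than in control and 1 at least 2-fold lower. miR-146a-5p, an NF-kB-induced regulator of inflammatory signalling, was 7.17-fold higher (log2 ratio 2.84, SE of spots 0.02). The epithelial miR-200b-3p, miR-429-3p and miR-200a-3p were 2.81-, 2.79- and 2.65-fold higher, and their median with the other 2 family members lay at percentile 100 of matched lists. miR-148a-3p was 2.91-fold, miR-221-3p 2.82-fold, miR-21-3p 2.37-fold, miR-338-3p 2.32-fold and miR-149-5p 2.03-fold higher, and miR-3102-5p was 2.78-fold lower. The Sfmbt2 cluster had a median of 0.38 at percentile 99.7 with 0 of 26 members at 2-fold, signal shared between members again not tested. The miR-30 family had a median of -0.16 at percentile 2.4. The remaining lists with at least 3 members lay between percentiles 3.9 and 96.1. miR-210-3p had a ratio of -0.21.

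In OE cells 3 of 234 miRNAs were at least 2-fold higher than in control and 7 at least 2-fold lower. miR-146a-5p was 5.79-fold, miR-221-3p 2.64-fold and miR-29b-1-5p 2.48-fold higher. miR-3102-5p was 3.31-fold, miR-3960 2.64-fold, miR-5126 2.59-fold, miR-211-3p 2.56-fold, miR-2861 2.31-fold, miR-5105 2.20-fold and miR-200a-3p 2.06-fold lower. The miR-200 family, at percentile 0.04 with a median of -0.84, thus lay on the other side of control than in KD. The pro-angiogenic list lay at percentile 98.3 (median 0.29, and percentile 85.0 with quantile normalization). The list of miRNAs reported to restrain angiogenesis lay on the same side, at 97.4 (0.36). The miR-17~92 family lay at 98.7 (0.38) and the high-GC list at 1.5 (-0.31). The remaining lists with at least 3 members lay between 8.1 and 97.4. miR-210-3p had a ratio of 0.53. The order KD over control over OE was seen at 1.5-fold for 3 of 231 cellular miRNAs, miR-200a-3p, miR-200b-3p and miR-429-3p, and the opposite order for 0. The 3 became 0 with normexp, 1 at 2-fold and 4 without scaling, with the software's detection flag or with the summed signal.

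**Figure D3:**
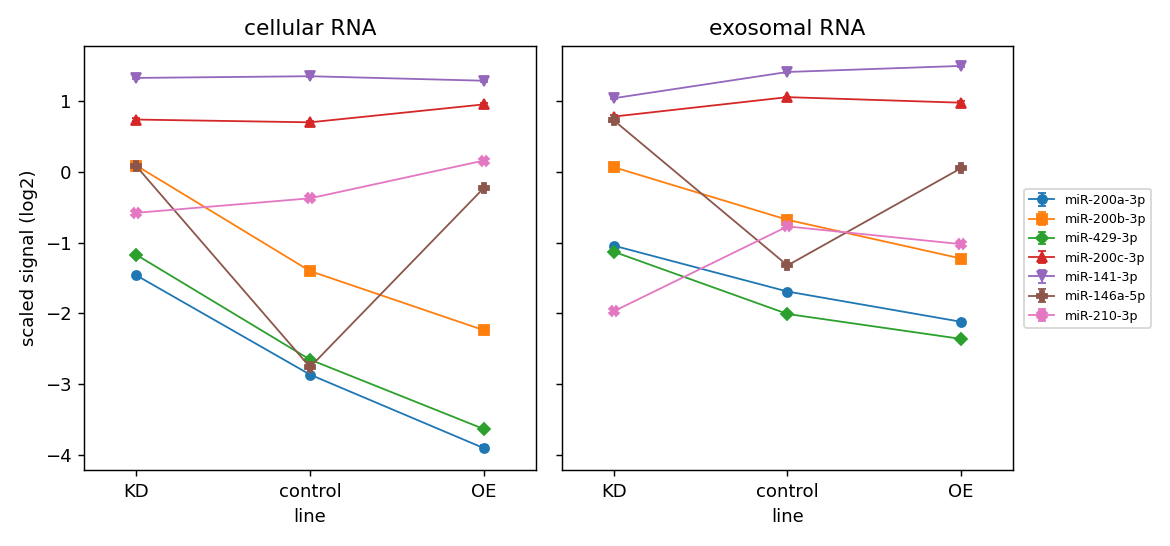
Scaled signal (log2, vertical axis) of the miR-200 family, miR-146a-5p and miR-210-3p in each line (horizontal axis) for cellular RNA (left) and exosomal RNA (right), 1 array per point; bars are the SE of the spots, mostly smaller than the symbols, and lines join the values of 1 miRNA. In cells miR-200b-3p was 0.09 in KD, -1.40 in control and -2.24 in OE, whereas miR-200c-3p lay between 0.70 and 0.96; in exosomes miR-200b-3p was above control in KD, a ratio of 0.74 that turned to -1.38 without scaling.

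Export ratios asked whether exosomal differences went beyond cellular ones. Of 230 miRNAs detected on all 4 arrays concerned, 27 had an export ratio at least 2-fold higher in KD than in control and 16 at least 2-fold lower. In OE, where 9 fewer were compared, these were 23 and 6. The highest differences in KD were those of miR-466h-3p (4.22), miR-466f-3p (4.03) and miR-467f (3.91), of which the first and last are minimum values, and in OE those of miR-709 (5.27) and miR-5107 (3.97). The lowest were miR-1982-5p (-3.96, with cellular values at the floor) in KD and miR-5121 (-1.78) in OE. miR-146a-5p had a difference of -0.79 in KD and -1.16 in OE. Without scaling the counts were 6 and 197 in KD and 6 and 189 in OE.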

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

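All tests in this part but the test of a trend with signal were chosen after the results were seen. Of the control-type probes, not used in the comparisons and of a kind the files do not describe, 6 gave signal on all 6 arrays. Their signal on the control exosomal array was 9.20 times (hur_1), 11.8 times (hur_2), 29.8 times (hur_4), 1.94 times (hur_6), 7.71 times (mr_1) and 0.800 times (miRNABrightCorner30) the mean of the KD and OE exosomal arrays. Among the cellular arrays the highest was 1.07, 1.28, 1.10, 1.31, 1.5 and 1.47 times the lowest, in the same sequence.

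The exosomal minus cellular difference had opposite signs in different lines for some named miRNAs. Each line has 1 sample per compartment, and the difference between lines was not tested. The log2 difference was 3.54 in KD and 2.92 in OE for miR-466f-3p, 3.62 and 2.85 for miR-466h-3p, 3.22 and 2.50 for miR-466i-3p, 3.19 and 2.33 for miR-467f and 2.71 and 4.40 for miR-709, all below 0 in the control line, from -0.87 to -0.45. In KD it was -0.66 for miR-5105 and -1.62 for miR-5121, against 2.14 for each in control. Without scaling the control differences of the first 5 were above 0, from 1.28 to 1.85, so the lines no longer had opposite signs. With normexp that of miR-466i-3p was 0, and with the summed signal that of miR-466f-3p was 0.28. The control exosomal values of miR-466h-3p, miR-466i-3p and miR-467f were at the floor.

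The KD and OE exosomal ratios to control varied together over miRNAs, with a covariance of 0.93, while 67.1% had the same sign in both, against 66.6% simulated for unchanged arrays with the cellular spread. A trend with signal is argued against, since Spearman's rho of the mean ratio with the mean signal over miRNAs was -0.056. Array brightness and scaling stay open, because no repeat exosomal array gives the spread to judge the covariance by. The covariance was 0.83 with quantile normalization and 0.47 with normexp, where the variance of the KD ratios also fell, from 1.60 to 0.76. The correlation was 0.73 with quantile normalization and 0.77 with normexp, against 0.74 here. It also stays open that the single control exosomal array stands apart by itself, because the design holds no repeat of it. A change shared by both engineered lines stays open too: the cellular covariance of 0.086 cannot decide this, since the simulated spread came from the same cellular arrays.

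In cells, miR-200a-3p, miR-200b-3p and miR-429-3p, which lie together on mm9 chromosome 4, were higher in KD and lower in OE. Signal shared with the similar miR-200c-3p and miR-141-3p is argued against, because the largest change of these was 0.25 on the log2 scale and the smallest of the 3 was 0.84. Scaling is argued against, because the smallest change in the same direction under any alternative was 0.36. Noise of the single cellular arrays stays open. Exosomal KD was above OE by 1.08 to 1.29 for these 3, and by 0.80 to 1.45 under the alternatives. This was 1.97 to 2.89 times the SE from the residuals of the model of line and compartment. With 2 residual degrees of freedom before moderation, such ratios cannot decide the question. Without scaling the ratio was 0.957 for miR-200a-3p, where the difference was 1.18 but the SE 1.23 in place of 0.55. With quantile normalization it ran up to 4.23 for miR-200b-3p. A difference between the cultures apart from nSMase2 cannot be told apart from an effect of nSMase2, because each line was cultured once as far as the labels say, and miR-146a-5p (2.84 in KD) differed from control in the same direction in both lines; a response to nSMase2 may be stated as a hypothesis only.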

How the results depend on the processing

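Leaving out lines, the comparison without blood markers, limma's trend and robust options, set together as planned, and the rescaled summed signals aside, each alternative changed a single choice. The summed signal per miRNA was first run with the software's detection flag and scaled over miRNAs in place of probes (rescaled), then rescaled without the flag, both chosen after the data were seen; the change of the summary alone, which was planned, was run last, after these results were seen. The run without the blood, serum, endothelial and vesicle lists was also chosen after the data were seen and gave 26 higher and 24 lower exosomal calls. Of the counts under an alternative, 184 were within 1.5 times and 94 were not; the cause was not tested unless named. Exosomal calls, 36 higher and 24 lower, became 75 and 4 with no scaling, 21 and 77 with quantile normalization, 90 lower with the percentile over all probes, and 15 higher with normexp, 23 with the mean over probes, 62 with the summed signal, 59 with it rescaled and 73 with the rescaled summed signal and flag, 19 among miRNAs detected on all 6 arrays (fewer were tested) and 59 with no floor. Leaving out a line in turn gave 0 to 62 higher and 0 to 19 lower, with 0 when the OE line was left out and 19 lower without the control line. Lists past camera, 2, became 4 with the mean over probes or the software's detection flag, 1 with no floor or the rescaled summed signal and 0 with an estimated correlation, and ran from 1 to 2 with a line left out.

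In KD exosomes, 53 higher and 27 lower became 12 and 242 with no scaling, 35 higher with quantile or normexp, 54 lower with the rescaled summed signal and flag, 29 and 14 among miRNAs on all 6 arrays, 82 higher with no floor and 97 and 41 at 1.5-fold. In OE exosomes, 38 and 15 became 7 and 255 with no scaling, 27 lower with the percentile over all probes, 24 higher with normexp, 65 higher with the summed signal, 69 with it rescaled, 66 and 29 with the rescaled summed signal and flag, 23 and 9 on all 6 arrays, 62 higher with no floor and 63 and 34 at 1.5-fold. In KD cells, 9 and 1 became 4 and 0 with normexp, 3 lower with no scaling, 2 lower with the percentile over all probes, quantile, the detection flag or no floor, 6 lower with the rescaled summed signal, 12 lower with the rescaled summed signal and flag and 26 and 8 at 1.5-fold. In OE cells, 3 and 7 became 2 lower with normexp, 6 and 11 with the summed signal, rescaled or not, 21 lower with the rescaled summed signal and flag and 17 and 20 at 1.5-fold.

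miRNAs with KD under control under OE in exosomes, 5, became 3 with the percentile over all probes, quantile or a 2-fold threshold, 1 with no scaling or on all 6 arrays, 2 with normexp and 10 with the rescaled summed signal and flag. The opposite order, 0, became 2 with the percentile over all probes and 1 with quantile, the mean over probes or the rescaled summed signal and flag. In cells the opposite order, 3, became 0 with normexp and 1 at 2-fold. Export ratios, 27 and 16 in KD and 23 and 6 in OE, became 6 and 197 and 6 and 189 with no scaling, 39 higher in OE with the summed signal and 42 with it rescaled, 28 lower in KD and 49 and 12 in OE with the rescaled summed signal and flag, 35 higher in OE with no floor and 18 lower in OE with the percentile over all probes. Lists outside percentiles 2.5 to 97.5 numbered 4 of 18 for KD exosomes and became 2 with quantile, the mean over probes or on all 6 arrays; for OE exosomes 1 of 17 became 2 with quantile and 0 with normexp, the mean over probes or any summed signal; for KD cells 3 of 16 and OE cells 4 of 15 stayed within 1.5 times.

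With no scaling single miRNAs turned sign: miR-29c-3p between compartments (0.13), miR-146a-5p (-0.068), miR-451 (-0.65) and miR-223-3p (-0.44) in KD exosomes, and miR-146a-5p (-0.84), miR-208a-5p (-0.14), miR-31-5p (-0.90), miR-1224-5p (-0.93), miR-3081-5p (-1.30), miR-680 (-0.86) and miR-762 (-1.01) in OE exosomes. miR-128-3p between compartments was -0.073 with quantile normalization. The ratio came to 0 for miR-3081-5p, miR-680 and miR-208a-5p in KD exosomes with normexp and for miR-1224-5p in OE exosomes with quantile normalization. Scaling by spike-ins was not run because the probes for them were at background on all arrays, and a slide or scan block was not run because there was 1 of each. The mean signal of negative control spots was 0.25 to 2.35, with an SD of 2.66 to 5.34. The lowest unscaled signal of a detected probe was 14.7 to 21.3 over the arrays, so the dimmest detected miRNAs rest on low signal.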

Other observations

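All tests in this part were chosen after the results were seen. Strands of the same miRNA differed between compartments: miR-21-5p had an exosomal minus cellular log2 ratio of -0.04, and miR-21-3p -1.97, a minimum size because its exosomal values were at the floor. The 2 strands of miR-5117 were both lower in exosomes (-2.77 and -2.70, minimum sizes for the same reason), and both members of the miR-451 and miR-144 pair were higher. miR-146a-5p was higher in cells and exosomes of both engineered lines, with log2 ratios of 2.84 and 2.53 in cells and 2.05 and 1.38 in exosomes, of which both exosomal values turned sign without scaling.

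Blood and liver miRNAs were measured in exosomal RNA and not in the cells. A candidate explanation is RNA from the fetal calf serum in the medium, as bovine and mouse forms of many miRNAs share their sequence. Of the erythroid, liver and leukocyte list members measured on all 3 exosomal arrays, 66.7% (6 of 9) were measured on no cellular array, against 14.1% (39 of 277) of the other miRNAs. This share restates the pattern, and export would give it too, so it does not tell serum from export. Of the 12 markers on the array, 2 were measured on all 3 cellular arrays and 7 are in another list. The median bound of the 6 was 18.5-fold (range 1.64 to 1461), while the 75th percentile of the exosomal arrays was 1.23 to 5.06 times that of the cellular ones. Brighter exosomal arrays are argued against for miR-451, miR-142-3p and miR-144-3p only, with bounds of 1461, 46.5 and 32.4. They stay open for the other members, among them miR-122-5p, with bounds down to 1.64. Export of miRNAs that the cells make at low levels stays open, since the 1461-fold bound for miR-451 cannot exclude it. In KD exosomes the 6 were 0.83 to 1.61 higher than in control (median 1.29, log2), and in OE exosomes -0.23 to 0.90 (median 0.32), single arrays whose sign depends on the scaling.

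With 3 against 3 arrays, the 10 possible splits are too few for a share under 0.05. The real split gave 60 calls between compartments, as many as 1 of the 10 splits, and the highest of the others gave 0. Each of the others mixes the compartments, which puts the compartment difference into its residual. Some also hold both arrays of a line on 1 side. Their 0 calls are therefore no reference for the 60, and no conclusion is drawn from them.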
